A study of Rattus norvegicus with 9 samples.

How the data were processed

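Total RNA was isolated with Trizol from CD4+ T cells of the peripheral blood of rats, and libraries were made with an NEBNext Ultra RNA kit for Illumina, per the labels. How the CD4+ cells were selected is not described. Normal, model and combination groups held 3 libraries each, and each of the 9 samples had 1 table. The authors used bcl2fastq and HISAT2 with the rat genome rn6, whose versions are not given, and per the file headers StringTie 1.3.3b estimated the expression of a fixed, merged set of transcripts. The deposited tables gave coverage, FPKM and TPM, other text attributes of 80092 transcripts, as the authors' StringTie run computed them. Raw counts and read length are not given, so no counting intervals were derived, and normalized values were tested on a log scale. No genome sequence was at hand, so base composition was not checked.

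Depth was computed from the constant ratio of coverage to FPKM in each library and was 7.52 to 10.1 gigabases. Of the transcripts, 41066 came from the reference and 39026 were assembled, in 35817 loci. Transcript TPM was summed to gene units, each a reference gene name within an assembled locus. Assembled transcripts of a locus with several names were assigned by exon overlap (5378 transcripts). This gave 36858 units, 29379 with a gene name. Loci with at least 2 names numbered 844 and held 12.5% of TPM, and 381 names lay at 2 or more loci. Assembled transcripts held 30.7% of TPM.

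The groups, comparisons, tests, gene lists, rules for naming genes and most alternatives were chosen before the data were examined. Genes with a mean of at least 1 TPM over the 9 libraries (14175 of 30032 above 0 in any) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3. The fit had 1 coefficient per group and empirical Bayes moderation with an intensity trend, 6 residual and 3.53 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold, without a fold threshold. Tables were read and tested further in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. All adjusted p-values of genes and lists came from limma.

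The 35 gene lists were tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. They covered T cell identity, naive T cells, T cell activation, Th1, Th2, Th17, regulatory and follicular helper T cells. They also covered other blood cells (cytotoxic and NK, B, plasma, monocyte, neutrophil, platelet, erythroid, and class II and dendritic), signalling, stress and metabolism. Members were also adjusted over the list alone. Summed TPM of other-cell lists and of T cell identity was compared by an exact two-sided permutation test over 20 arrangements. The reversal test set the covariance of log2 fold changes against 100 data sets simulated without group effects, in which genes varied independently. Each simulated gene had the same spread in the 3 groups.

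Genes were named by rule. They were the 10 largest rises and 10 largest falls of a comparison among genes past the threshold with groups that did not overlap, at least 5 TPM in the higher group and a proper symbol. Clone names were also taken as lacking a proper symbol, a choice made after they were seen. Up to 4 members per list past the threshold, or else 2 of the smallest p, and a preset set of genes were tabulated, of which a part is printed; 1 preset gene is not reported here.

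The procedure was tested on simulated data with 200 changed genes in each of 5 rounds. It recovered 2% of 1.5-fold, 34% of 2-fold, 82% of 4-fold and 92.8% of 8-fold changes, with 5.78% false calls. A list of 20 genes shifted by 0.70 log2 was called in 10 of 10 rounds, and 0 of 300 unshifted lists were called. The simulated genes varied independently, so these rounds do not test list calls against correlation between genes. Each simulated gene also had the same spread in the 3 groups. The shares recovered and falsely called thus may not hold where the groups differ in spread.

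Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, FPKM, median-ratio scaling with factors of 0.901 to 1.16, and omission of haemoglobin, mitochondrial and ribosomal protein genes. Others were a fit of only the 2 groups compared, no intensity trend, array weights, the replicate number as a block, and omission of each library. Added after the data were seen were fits with model replicate 2 or combination replicate 2 alone kept in its group, locus sums, omission of genes under 300 bases, omission of members of other-cell lists, and counts of genes past the threshold in 2 comparisons with each library omitted. Whether equal replicate numbers pair the libraries was checked by the correlation of residuals, which was -0.14 to 0.056, and 1 of 9 libraries correlated best with its own number, so no pairing was used.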

Results

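The 9 libraries measured total RNA of CD4+ T cells from the peripheral blood of SD rats aged 8 to 10 weeks. They formed 3 groups of 3 libraries: normal rats, CIA rats (the model group) and CIA rats given a combination of compounds for 4 weeks (the combination group). CIA was read as collagen-induced arthritis, since the title of the series concerns rheumatoid arthritis, and the labels do not name the compounds. Per the file headers the combination libraries were processed under sample names other than those of the labels, and the groups of the labels were used. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries. The aligned depth was 8.95, 8.35 and 9.07 gigabases in normal replicates 1, 2 and 3. It was 9.86, 8.04 and 10.1 gigabases in model replicates 1, 2 and 3, and 7.77, 8.12 and 7.52 gigabases in combination replicates 1, 2 and 3. Between 86.7% and 89.0% of these bases lay in the listed transcripts. Read length is not given, so read counts and their counting error could not be derived.

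Expression was compared for 14175 genes with a mean of at least 1 TPM, the length-corrected unit of the deposited tables, over the 9 libraries. Genes that mark T cells were abundant in each group. Cd3e averaged 431 ± 3.83, 288 ± 101 and 361 ± 48.6 TPM and Cd4 222 ± 17.3, 121 ± 58.0 and 121 ± 22.1 TPM in the normal, model and combination groups (mean ± SD, n = 3). Cd8a, of cytotoxic T cells, averaged 6.81, 4.38 and 5.78 TPM and Cd79a, of B cells, 6.02, 2.82 and 3.82 TPM. On the first principal component, with 27.6% of the variance, the normal libraries lay between -40.4 and -30.9. Model replicates 1 and 3 lay at 39.3 and 57.4, while model replicate 2 lay at 0.259, among the combination libraries at -3.85 to 8.10. The second component, with 22.1%, held the combination libraries at -42.4 to -33.6 and the other 6 at 11.3 or more.

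The model group was compared with the normal group to ask how blood CD4+ T cells differed in arthritic rats. Smad7, an inhibitor of TGF-beta signalling, rose from 31.5 ± 11.2 to 310 ± 150 TPM (n = 3 per group), and Dusp2, a phosphatase that acts on MAP kinases, from 128 ± 44.7 to 1170 ± 666 TPM. Relb and Nfkb2, subunits of NF-kB in its non-canonical pathway, rose from 19.7 ± 3.77 to 144 ± 43.3 TPM and from 34.5 ± 17.4 to 207 ± 54.8 TPM. Txnip, which binds thioredoxin and restrains glucose uptake, fell from 793 ± 161 to 118 ± 34.2 TPM. Ctla4, an inhibitory receptor of T cells, fell from 46.0 ± 1.41 to 12.3 ± 7.06 TPM.

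In all, 707 genes differed between model and normal at an adjusted p under 0.05, of which 403 were higher and 304 lower in the model group. Changes of at least 2-fold numbered 253 and 210. Genes under 300 bases were 5 of the higher and 92 of the lower genes. In a fit without such genes 377 were higher and 207 lower. The higher share of 57.0% was 48.2% of 1223 genes without haemoglobin, mitochondrial and ribosomal protein genes and 68.3% of 559 genes with a mean of at least 5 TPM. The 3 libraries of either group lay entirely apart for 33.2% of genes, against 10% by chance. The count moved with single libraries: it was 79, 34 and 65 without normal replicates 1, 2 and 3, and 225, 2813 and 143 without model replicates 1, 2 and 3. With only the 2 groups fitted, so that the combination libraries did not enter the spread, it was 113. With the replicate number as a block it was 163.

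Smad7 (rn6 chromosome 18, 71395620 to 71424157) had a log2 fold change of 3.21 ± 0.434 (SE, adjusted p = 0.013). Txnip (chromosome 2, 198683159 to 198686974) had one of -2.76 ± 0.232 (adjusted p = 0.00328), and Ctla4 (chromosome 9, 67699379 to 67706065) one of -1.94 ± 0.294 (adjusted p = 0.0165). The other largest rises in log2 fold change were Hba-a2 (4.11) and Alas2 (2.88), of haemoglobin and haem synthesis; F2r (3.66), the thrombin receptor; Ern1 (3.15), a sensor of unfolded proteins; Dusp2 (3.09); Cks2 (3.07), which binds cyclin-dependent kinases; the metallothionein Mt2A (3.00); Kdm6b (2.99), a histone demethylase; and Ski (2.89), a repressor of TGF-beta signalling. The other largest falls were SNORD34 (-3.36), SNORD33 (-2.29) and SNORD14 (-1.98), which are small nucleolar RNA genes of under 300 bases, Bbof1 (-2.76), the neutrophil genes S100a9 (-2.30) and S100a8 (-2.23), Sap25 (-1.97) and the GTPase Rhoc (-1.92). SNORD34 was listed near 0 TPM in the model libraries, so its log2 fold change rests on the pseudocount: it was -6.44 with 0.1 and -1.58 with 5. Other genes of few TPM in 1 group moved with it too, among them S100a8 (-3.65 and -1.09), Bbof1 (-3.68 and -1.48), Alas2 (3.92 and 1.70) and F2r (4.42 and 2.39). F2r, Kdm6b, Sap25, SNORD33 and SNORD34 share an assembled locus with at least 1 other named gene, and Hba-a2 has close copies. Of 68 named genes past the threshold here, 5 (Cks2, Klrk1, Lta, Relb and Txnip) stayed past it in each of the 6 fits that left out 1 library. The call ended for 54, 62 and 59 of them without normal replicates 1, 2 and 3 and for 38, 0 and 45 without model replicates 1, 2 and 3, and none turned.

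Genes controlled by NF-kB were higher as a group. Of 24 measured, 10 rose and none fell, or 14 and 0 adjusted over the list alone. Their median log2 fold change was 1.14 (camera adjusted p = 4.52e-08; adjusted p = 0.733 with an estimated correlation). Beside Relb (2.78) and Nfkb2 (2.62), Bcl3 (2.56), a nuclear partner of NF-kB, Cd83 (2.26) and Nfkbia (1.07), the inhibitor of NF-kB, rose. Of 23 immediate early genes, which respond within minutes to stimuli, 4 rose and none fell, or 10 and 0 adjusted over the list alone. Their median was 0.92 (adjusted p = 0.000512; adjusted p = 0.733 with an estimated correlation). Dusp2, Maff (1.68), Junb (1.18) and Rgs1 (0.98) rose. With model replicate 2 alone kept, the immediate early list had a median of 0.30 with a test downward (adjusted p = 0.94). Of 19 inflammatory cytokine and chemokine genes, Lta, which encodes lymphotoxin alpha, rose from 2.13 ± 0.427 to 15.2 ± 2.98 TPM and none fell, or 2 and 0 adjusted over the list alone. That list had a median of 0.53 (adjusted p = 0.013; adjusted p = 0.733 with an estimated correlation). Its call ended without normal replicate 2 (median 0.21, adjusted p = 0.0899), without model replicate 1 (adjusted p = 0.0745) and with a mean of at least 5 TPM (adjusted p = 0.0654). With model replicate 2 alone kept the median of the inflammatory list was 0.39.

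Genes of the unfolded protein response were also higher. Of 20 measured, 7 rose and none fell, or 11 and 0 adjusted over the list alone. Their median was 0.69 (adjusted p = 1.67e-05; adjusted p = 0.733 with an estimated correlation). Chac1 (2.18) and Trib3 (2.07), targets of the stress factor ATF4, Calr (1.44), a chaperone of the endoplasmic reticulum, and Xbp1 (1.17), a transcription factor of the response, were among them. Of 17 TGF-beta signalling genes, 4 rose and none fell, or 9 and 1 adjusted over the list alone. Their median was 0.77 (adjusted p = 3.97e-05; adjusted p = 0.733 with an estimated correlation). The members that rose, Smad7, Ski, Skil (2.66) and Tgif1 (1.28), are known as repressors of the pathway.

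Cholesterol synthesis genes had 3 risen of 22 and none fallen, or 7 and 1 adjusted over the list alone, with a median of 0.47 (adjusted p = 0.0018; adjusted p = 0.733 with an estimated correlation). Cyp51 (1.21) and Sc5d (0.85), enzymes of sterol synthesis, and Insig1 (1.17), which restrains it, rose; without model replicate 2 the list had an adjusted p of 0.0578. Of 28 mTOR and autophagy genes 3 rose and none fell, or 6 and 0 adjusted over the list alone, with a median of 0.22 (adjusted p = 0.0172; adjusted p = 0.79 with an estimated correlation). They were Ulk1 (1.75), the kinase that starts autophagy, Sqstm1 (1.19) and Gabarapl2 (0.98); the adjusted p was 0.085 without model replicate 3 and 0.0654 with a mean of at least 5 TPM. Of 22 cell cycle genes, Mcm5 (1.14), a part of the replicative helicase, rose and none fell, or 5 and 0 adjusted over the list alone, with a median of 0.25 (adjusted p = 0.014; adjusted p = 0.733 with an estimated correlation). That list had an adjusted p of 0.0578 without model replicate 2 and of 0.153 with a mean of at least 5 TPM.

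Lists that were lower in the model group were those of ribosomal proteins and of T cell identity. Of 85 ribosomal protein genes 1 rose and 1 fell, with the same counts adjusted over the list alone, and the median was -0.14 (adjusted p = 0.000729; adjusted p = 0.733 with an estimated correlation). Rplp2, of the ribosomal stalk, fell by 0.61 and a copy of Rps2 rose by 2.07. None of 21 genes of T cell identity and receptor signalling passed the test, also adjusted over the list alone, and the median was -0.33 (adjusted p = 0.0266; adjusted p = 0.79 with an estimated correlation). Cd4 had a log2 fold change of -0.98 (adjusted p = 0.0779) and Cd27 one of -0.82 (adjusted p = 0.081). The call ended without normal replicate 2 (adjusted p = 0.0519) and without model replicate 1 (adjusted p = 0.136). With model replicate 2 alone in its group the median was -0.033 (adjusted p = 0.525), and Cd4 was 186 TPM in that library and 76.5 and 99.1 TPM in model replicates 1 and 3.

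Markers of red cell precursors moved with the model group. Of 9 erythroid genes 3 rose and none fell, or 4 and 0 adjusted over the list alone, with a median of 0.53 (adjusted p = 0.0268; adjusted p = 0.733 with an estimated correlation). Hba-a2 averaged 357 ± 385 and 4986 ± 5149 TPM, Alas2 1.45 ± 1.53 and 20.7 ± 21.8 TPM, and Hba-a3 rose by 2.82. Hbb averaged 145 ± 162 and 2286 ± 2505 TPM (adjusted p = 0.0512). The erythroid call ended without normal replicate 1 (adjusted p = 0.0501), without model replicate 1 (adjusted p = 0.0516) and without model replicate 2 (adjusted p = 0.0587). It also ended with median-ratio scaling (adjusted p = 0.0669), with only the 2 groups compared (adjusted p = 0.0646) and without haemoglobin, mitochondrial and ribosomal protein genes (adjusted p = 0.198). The summed erythroid TPM was 16252, 3398 and 2446 in model replicates 1, 2 and 3, beside 368, 88.8 and 1153 in normal replicates 1, 2 and 3. Hba-a2 and Hbb made up 10917 and 5175 TPM of the sum in model replicate 1.

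The remaining lists did not pass in this comparison, although some members did. Among genes of T helper subsets, Rora (1.23) rose in the Th17 list (median 0.63, adjusted p = 0.108), and Cxcr5 (1.37) rose and Sh2d1a (-0.62) fell in the T follicular helper list (median 0.63, adjusted p = 0.495). The Th1 list had a median of 0.39 (adjusted p = 0.0973), in which Tbx21, the master regulator of Th1 cells, had a log2 fold change of 1.20 (adjusted p = 0.0611). The Th2 list had a median of 0.48 (adjusted p = 0.394), the regulatory T cell list 0.14 (adjusted p = 0.845; negative with median-ratio scaling and with FPKM) and the naive T cell list 0.083 (adjusted p = 0.585). In the T cell activation list (median 0.19, adjusted p = 0.729) Irf4 (1.37) rose and Ctla4 fell. Foxp3 averaged 18.0 ± 3.59 and 24.7 ± 2.59 TPM in the normal and model groups (adjusted p = 0.197), and Il17a and Mki67 lay below the filter. The NK cell receptors Klrk1 (-1.55) and Klrd1 (-1.84) fell in the cytotoxic and NK cell list (median -0.33, adjusted p = 0.0973).

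Pim2 (1.88), Socs3 (1.51), Cish (1.48) and Il6st (0.87) rose among JAK-STAT genes (median 0.12, adjusted p = 0.137). Hk2 (1.40) and Pfkfb3 (1.47) rose and Tpi1 (-1.17) fell among glycolysis genes (median -0.13, adjusted p = 0.598). Icam1 (1.75) and Cd99 (1.06) rose and Cd226 (-1.19) and Icam2 (-0.71) fell among adhesion genes (median -0.32, adjusted p = 0.423). Mt2A and Mt1 (1.40) rose and Txnip and Tsc22d3 (-1.40) fell among glucocorticoid response genes (median 0.11, adjusted p = 0.642). Bcl2l11 (1.79) and Gadd45b (1.68) rose among apoptosis and p53 genes (median 0.10, adjusted p = 0.379). Interferon-stimulated genes had a median of -0.12 (adjusted p = 0.209), heat shock genes -0.034 (adjusted p = 0.851), and oxidative stress genes 0.17 (adjusted p = 0.68). Nuclear-encoded oxidative phosphorylation genes had a median of 0.040 (adjusted p = 0.241), negative with FPKM and without haemoglobin, mitochondrial and ribosomal protein genes. Mitochondrially encoded genes had a median of -0.29 and a mean of 0.18 (test downward, adjusted p = 0.136), with Mt-nd2 fallen by 0.65 in a locus of 7 gene names. The plasma cell list had a median of 0.42 (adjusted p = 0.0939), the monocyte list 0.22 (adjusted p = 0.209), the platelet list 0.42 (adjusted p = 0.241), the class II and dendritic cell list 0.47 (adjusted p = 0.209), the B cell list -0.49 (adjusted p = 0.11) and the neutrophil list -0.29 (adjusted p = 0.244).

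**Figure D1:**
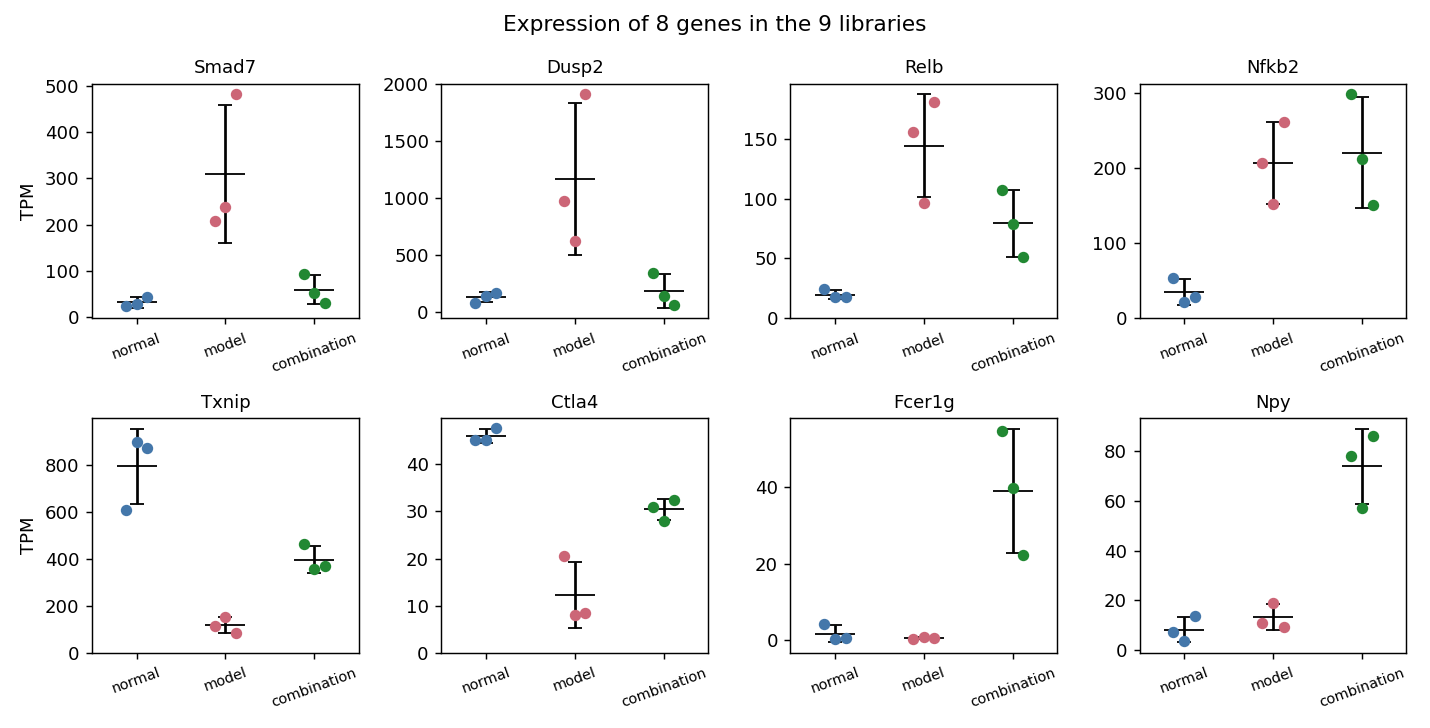
Expression in TPM (y axis, linear) of 8 genes in the 9 libraries, by group on the x axis. Each point is a library, the long bar the mean and the whiskers the SD (n = 3). Smad7 and Dusp2 were highest and Txnip and Ctla4 lowest in the model libraries, Relb had its highest mean there, Nfkb2 was higher in both arthritic groups, and Fcer1g and Npy were highest in the combination libraries.

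The combination group was compared with the model group to ask how arthritic rats given the compounds differed. Whether the combination libraries were also processed apart is not given, so such a difference cannot be told apart from the compounds. Genes that had been high in the model group were lower: Dusp2 fell from 1170 ± 666 to 185 ± 145 TPM (n = 3 per group) and Smad7 from 310 ± 150 to 58.8 ± 31.4 TPM. Jund, a subunit of the AP-1 transcription factor, fell from 2701 ± 110 to 1209 ± 59.2 TPM, below its normal 2384 ± 131 TPM. Txnip rose from 118 ± 34.2 to 397 ± 56.9 TPM and Ctla4 from 12.3 ± 7.06 to 30.4 ± 2.19 TPM. Genes of myeloid cells and platelets were higher: Fcer1g, the signalling chain of Fc receptors, rose from 0.597 ± 0.163 to 38.9 ± 16.2 TPM, and Pf4, platelet factor 4, from 17.7 ± 7.74 to 70.1 ± 19.8 TPM. The neuropeptide gene Npy rose from 13.2 ± 5.21 to 73.7 ± 15.0 TPM.

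Here 636 genes passed, 342 higher and 294 lower in the combination group, with 218 and 166 of them changed by at least 2-fold. Genes under 300 bases were 64 of the higher and 2 of the lower genes. In a fit without such genes 271 were higher and 281 lower. The groups lay apart for 26.9% of genes, against 10% by chance. The higher share of 53.8% was 38.3% of 1630 genes with median-ratio scaling and 65.7% of 1426 genes without haemoglobin, mitochondrial and ribosomal protein genes, where the median of all genes was 0.13 in place of 0.034. The count was 261, 1305 and 35 without model replicates 1, 2 and 3, and 44, 31 and 358 without combination replicates 1, 2 and 3. With only the 2 groups fitted, so that the normal libraries did not enter the spread, it was 24. With the replicate number as a block it was 9.

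Fcer1g (rn6 chromosome 13, 89601896 to 89606326) had a log2 fold change of 4.56 ± 0.505 (SE, adjusted p = 0.0101) and Npy (chromosome 4, 79557854 to 79565097) one of 2.43 ± 0.394 (adjusted p = 0.0259). The other largest rises were Lmo2 (2.52), a regulator of blood progenitors, Csf1r (2.41), the receptor of macrophage growth factor, Clec1b (2.31), Pf4 (1.96) and Nrgn (1.96), of platelets, the scavenger receptor Cd36 (2.26), the kinase Fgr (2.07) and Btbd11 (2.06). The other largest falls were Alas2 (-2.92), Dusp2 (-2.83), Hba-a3 (-2.81), F2r (-2.78), Grasp (-2.69), the corepressor Bcor (-2.64), Id3 (-2.56), an inhibitor of transcription factors, the signalling regulator Rgs16 (-2.53), Tmem206 (-2.51) and Spsb1 (-2.46). The value of Fcer1g, under 1 TPM in the model libraries, was 5.74 with a pseudocount of 0.1 and 2.90 with 5. Fcer1g, Cd36 and F2r share an assembled locus with at least 1 other named gene. Fcer1g did not keep step with the myeloid genes Tyrobp and Lyz2. These averaged 27.7 and 84.9 TPM in the model group and 112 and 370 TPM in the combination group. The cause of this difference was not tested. Of 59 named genes past the threshold, 3 (Clec1b, Fcer1g and Jund) stayed past it in each of the 6 fits that left out 1 library. The call ended for 34, 6 and 54 of them without model replicates 1, 2 and 3 and for 51, 55 and 33 without combination replicates 1, 2 and 3, and none turned.

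Genes of the unfolded protein response were lower in the combination group. Of 20 measured, 6 fell and none rose, or 12 and 0 adjusted over the list alone, with a median of -0.58 (adjusted p = 1e-06; adjusted p = 0.751 with an estimated correlation). Trib3 (-1.62), Sdf2l1 (-1.37), Xbp1 (-1.19) and Calr (-1.11) were among them. Of 23 immediate early genes 3 fell and none rose, or 6 and 0 adjusted over the list alone, with a median of -0.73 (adjusted p = 4.67e-05; adjusted p = 0.751 with an estimated correlation). They were Dusp2, Maff (-1.52) and Jund (-1.16), while Jun averaged 2197 ± 1219 and 473 ± 346 TPM (adjusted p = 0.0746). That list had a median of -0.17 with a test upward (adjusted p = 0.922) with model replicate 2 alone kept. Of 22 cell cycle genes 3 fell and none rose, or 7 and 0 adjusted over the list alone, with a median of -0.27 (adjusted p = 0.00321; adjusted p = 0.751 with an estimated correlation). They were Mcm5 (-1.13), Stmn1 (-1.10), which binds tubulin, and Cdca8 (-1.09), of the chromosomal passenger complex.

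Of 17 TGF-beta signalling genes 3 fell and none rose, or 5 and 2 adjusted over the list alone, with a median of -0.60 (adjusted p = 0.032; adjusted p = 0.867 with an estimated correlation). They were Smad7 (-2.41), Tgif1 (-1.36) and Tgfb1 (-1.25), which encodes TGF-beta 1. That call ended without model replicate 1 (adjusted p = 0.0733), model replicate 3 (0.172) or combination replicate 3 (0.0638), and with median-ratio scaling (0.0849). It also ended with model replicate 2 alone kept, where the median was -0.099 (adjusted p = 0.915), and with combination replicate 2 alone kept (adjusted p = 0.063). Of 23 glycolysis genes 3 fell and none rose, or 3 and 2 adjusted over the list alone, with a median of -0.37 (adjusted p = 0.0197; adjusted p = 0.867 with an estimated correlation). They were Hk2 (-1.34), hexokinase 2, and the phosphofructokinases Pfkl (-1.36) and Pfkp (-0.82), and the adjusted p was 0.32 without model replicate 2 and 0.178 with array weights. Of 17 heat shock genes, Hsp90ab1 (-0.73), a cytosolic chaperone, fell and none rose, or 3 and 0 adjusted over the list alone, with a median of -0.19 (adjusted p = 0.0233; adjusted p = 0.867 with an estimated correlation). Its call ended without model replicate 3 (adjusted p = 0.0705) and without combination replicate 3 (adjusted p = 0.0513).

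Markers of platelets and monocytes were higher in the same combination libraries. Of 10 platelet and megakaryocyte genes 8 rose and none fell, with the same counts adjusted over the list alone, and the median was 1.35 (adjusted p = 1e-06; adjusted p = 0.751 with an estimated correlation; fry adjusted p = 0.03). Clec1b, Pf4, Nrgn and Gp1bb (1.80), of the von Willebrand factor receptor, were among them. Of 14 monocyte and macrophage genes 5 rose and none fell, or 10 and 0 adjusted over the list alone, with a median of 1.43 (adjusted p = 7.32e-05; adjusted p = 0.751 with an estimated correlation). They included Csf1r, Cd36, Clec4a3 (2.10) and Emilin2 (1.88). The summed monocyte TPM was 670, 591 and 338 in combination replicates 1, 2 and 3, beside 237, 138 and 120 in model replicates 1, 2 and 3. Lyz2 alone made up 453, 421 and 236 TPM of the combination sums. Of 14 cytotoxic and NK cell genes 2 rose and none fell, with the same counts adjusted over the list alone, and the median was 0.45 (adjusted p = 0.0201; adjusted p = 0.751 with an estimated correlation). They were Klrb1a (1.14) and Klrk1 (0.91), and the call ended without model replicate 3 (adjusted p = 0.106) and without combination replicate 3 (adjusted p = 0.263). It also ended with no filter (adjusted p = 0.0752), a mean of at least 5 TPM (0.106), FPKM (0.0879) and array weights (0.178). The median of this list was 0.153 with combination replicate 2 alone kept and 0.115 with model replicate 2 alone kept.

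Erythroid and plasma cell lists were lower. Of 9 erythroid genes 2 (Alas2 and Hba-a3) fell and none rose, or 6 and 0 adjusted over the list alone, with a median of -0.67 (adjusted p = 0.00321; adjusted p = 0.751 with an estimated correlation). The summed erythroid TPM was 896, 288 and 413 in combination replicates 1, 2 and 3, below each model library, as the unfolded protein response, immediate early and cell cycle lists were also lower. Of 8 plasma cell genes 2 fell and none rose, with the same counts adjusted over the list alone, and the median was -0.48 (adjusted p = 0.00999; adjusted p = 0.751 with an estimated correlation). Both, Xbp1 and Creld2 (-1.05), are also members of the unfolded protein response list.

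Other lists did not pass here. The NF-kB list, with none of 24 members past the threshold, had a median of -0.20 (adjusted p = 0.358), and Nfkbia averaged 699 ± 197 and 587 ± 146 TPM. The inflammatory list had a median of 0.36 and a mean of 0.13 with a test downward (adjusted p = 0.892). In it Tnfsf13 (1.35) rose, Lta (-1.53) and Tgfb1 fell, and Il1b, a cytokine of myeloid cells, had a log2 fold change of 2.23 (adjusted p = 0.0573). Tnfsf13 and Il1b stood beside the higher monocyte sum. Ctla4 (1.36) rose and Irf4 (-1.31) fell among T cell activation genes (median -0.11, adjusted p = 0.471), Ccr4 (-1.25) fell among Th2 (-0.39, adjusted p = 0.194) and Th17 genes (-0.051, adjusted p = 0.382), and Cxcr5 (-1.41) fell and Sh2d1a (0.59) rose among T follicular helper genes (-0.63, adjusted p = 0.382). Klf2 (-1.47), a regulator of T cell trafficking, fell in the naive T cell list (-0.11, adjusted p = 0.371). The T cell identity list had a median of 0.13 (adjusted p = 0.582). Medians and tests also differed in sign for glucocorticoid response genes (median -0.020, mean 0.16, test upward, adjusted p = 0.601) and for mTOR and autophagy genes (median 0.00053, mean -0.10, test downward, adjusted p = 0.382).

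**Figure D2:**
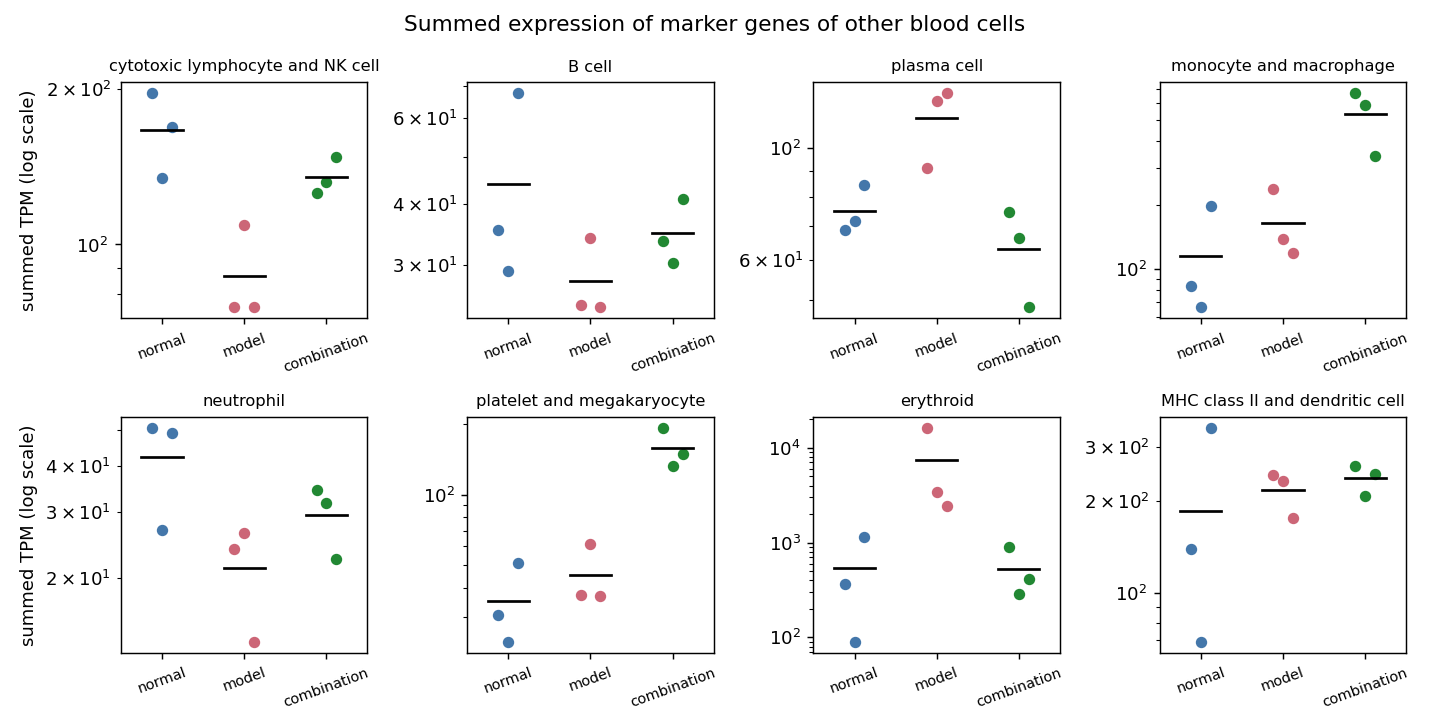
Summed TPM (y axis, log scale) of the marker genes of 8 other blood cell types in the 9 libraries, by group on the x axis. Each point is a library and each bar the group mean (n = 3). Monocyte sums were 338 to 670 in the combination libraries and 66.3 to 237 in the other 6, and erythroid sums were 2446 to 16252 in the model libraries and 88.8 to 1153 in the other 6. Lyz2 held most of the combination monocyte sums, and Hba-a2 and Hbb most of the model erythroid sums.

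The sums of marker genes were compared by an exact two-sided permutation test, in which 3 libraries against 3 give a smallest p of 0.1. Monocyte markers averaged 116 ± 71.2, 165 ± 63.4 and 533 ± 173 TPM and platelet markers 34.9 ± 14.4, 45.1 ± 14.2 and 158 ± 31.5 TPM in the normal, model and combination groups. Erythroid markers averaged 537 ± 552, 7365 ± 7710 and 533 ± 321 TPM. The exact p was 0.1 for the rise of monocyte and platelet markers against either group and for erythroid markers between model and either other group. It was also 0.1 for cytotoxic and NK cell and plasma cell markers between model and either other group, and for neutrophil markers between model and normal. Neutrophil markers averaged 42.3, 21.3 and 29.6 TPM, cytotoxic and NK cell markers 167, 86.8 and 135 TPM, plasma cell markers 75.1, 114 and 63.2 TPM, B cell markers 44.1, 27.8 and 35.0 TPM, and class II and dendritic cell markers 185, 218 and 237 TPM. T cell identity genes summed to 5404 ± 453, 4569 ± 689 and 4939 ± 379 TPM (exact p = 0.3 for model against normal and 0.7 for combination against model). Over the 9 sums of a comparison the smallest adjusted p was 0.18.

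Whether genes changed in the model group moved back in the combination group was tested across genes, which are not independent replicates. Of the 403 genes higher in the model group, 377 had a lower mean in the combination group, and of the 304 lower genes 282 had a higher mean. These genes were picked for their change, and both comparisons use the model libraries, which alone makes the changes run in opposite directions. In 100 data sets simulated without group effects, with genes drawn independently, the covariance of the log2 fold changes was -0.067 (SD 0.0040). The observed covariance was -0.18, which lay -0.11 beyond that mean. Genes of real libraries may vary together, which this SD leaves out. Each simulated gene also had the same spread in the 3 groups. Model libraries had a mean correlation of 0.943 to 0.955 with their own group, and normal and combination libraries 0.959 to 0.963. The simulated covariance may thus be too small in size, and the excess of -0.11 too large. Real differences between equally distant groups would also lie beyond the simulated covariance, so the covariance alone does not show a return to normal. Pearson's r was -0.53, against a simulated mean of -0.50, so r showed no such excess (Spearman's rho -0.47). Genes that rose in the model group and fell in the combination group numbered 102, and those that fell and rose 73, against 8.36 and 7.33 if the calls were independent, a number that does not allow for the shared model libraries. They were 9 and 12, 4 and 6, and 8 and 20 without normal replicates 1, 2 and 3, and 28 and 43, 432 and 358, and 7 and 10 without model replicates 1, 2 and 3. They were 10 and 6, 0 and 5, and 33 and 48 without combination replicates 1, 2 and 3, and 0 and 2 with the replicate number as a block, while the covariance was -0.29 to -0.15 in these fits. The first set included Smad7, Dusp2, F2r, Lta, Id3 (2.17 and -2.56), Klf10 (2.54 and -2.38) and Trib3. The second included Txnip, Ctla4, Klrk1 and Tagap (-1.69 and 1.28), a GTPase activator of T cells, and 33 of its 73 members were snoRNA genes, a class looked at after its values were seen. No gene rose in both comparisons and none fell in both. Of the 102, 101 did not pass the test between combination and normal, and of the 73, 70 did not, which does not show that they were equal.

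**Figure D3:**
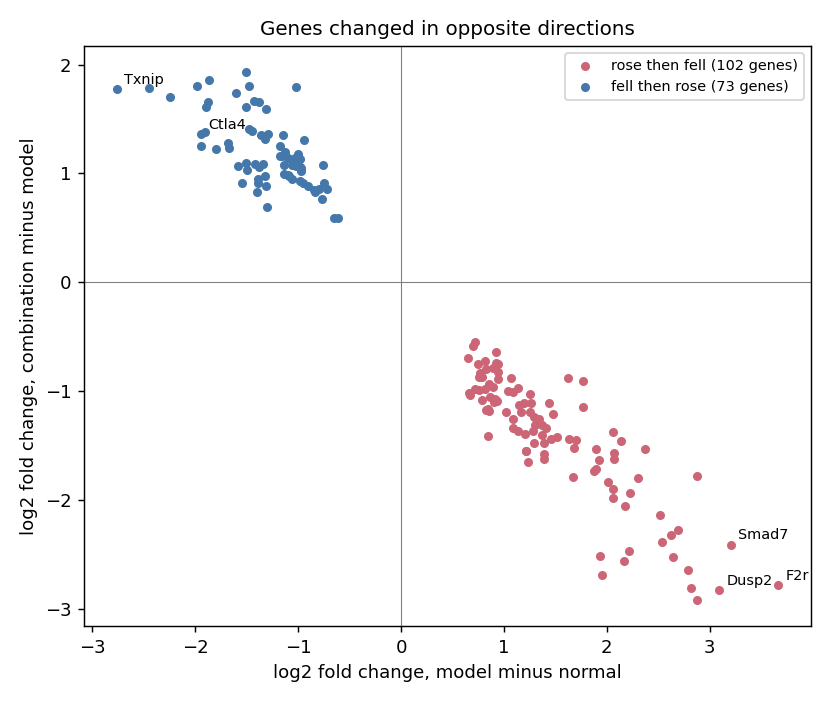
Log2 fold changes of the 175 genes that passed in both comparisons, in opposite directions, model minus normal on the x axis and combination minus model on the y axis. Each point is a gene: 102 rose and then fell, and 73 fell and then rose. Both axes use the model libraries, which alone tilts the points downward.

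The combination group was compared with the normal group to ask what still differed from healthy rats after treatment. Nfkb2 rose from 34.5 ± 17.4 to 221 ± 74.2 TPM (n = 3 per group) and Icam1, an adhesion molecule, from 10.8 ± 4.17 to 54.3 ± 20.7 TPM. Mt2A rose from 14.2 ± 11.6 to 102 ± 47.9 TPM. Lyz2, the lysozyme of myeloid cells, rose from 53.1 ± 48.8 to 370 ± 117 TPM. Cd96, a receptor of T and NK cells, fell from 19.5 ± 2.36 to 4.85 ± 0.251 TPM, and Itgb7, a homing integrin, from 47.0 ± 4.57 to 13.1 ± 1.97 TPM.

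In this comparison 652 genes passed, 372 higher and 280 lower, of which 251 and 160 changed by at least 2-fold, and the groups lay apart for 35.8% of genes, against 10% by chance. The higher share of 57.1% was 43.1% of 1501 genes with median-ratio scaling. The count was 30, 30 and 134 without normal replicates 1, 2 and 3, and 21, 52 and 728 without combination replicates 1, 2 and 3. With only the 2 groups fitted it was 1391, and with the replicate number as a block 82. Fcer1g (4.13 ± 0.505, SE, adjusted p = 0.0109), Npy (3.14 ± 0.394, adjusted p = 0.011), Lyz2 (3.10), Clec7a (3.06), Clec4d (3.04), Cybb (2.95), Mt2A (2.93), Clec1b (2.74), Pik3ap1 (2.73) and Nfkb2 (2.70) had the largest rises. Clec7a, Clec4d and Cybb are genes of myeloid cells. Bbof1 (-2.40), Lrrc23 (-2.09), S100a8 (-1.94), Mllt3 (-1.86), Chst11 (-1.84), Cd96 (-1.80), Fmnl3 (-1.80), Itgb7 (-1.77), Ssbp3 (-1.77) and a copy of Mcc (-1.77) had the largest falls. Of 62 named genes past the threshold, 3 (Clec1b, Jund and Nrgn) stayed past it in each of the 6 fits that left out 1 library. The call ended for 51, 56 and 38 of them without normal replicates 1, 2 and 3 and for 58, 53 and 13 without combination replicates 1, 2 and 3, and none turned.

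NF-kB target genes were higher in the combination group than in the normal group. Of 24 measured 5 rose and none fell, or 11 and 0 adjusted over the list alone, with a median of 0.84 (adjusted p = 2.75e-07; adjusted p = 0.938 with an estimated correlation). They included Nfkb2, Icam1 (2.21), Birc3 (1.95), an inhibitor of cell death, and Relb (1.91). Platelet genes had 6 risen of 10 and none fallen, or 7 and 0 adjusted over the list alone, with a median of 2.00 (adjusted p = 2.75e-07; adjusted p = 0.938 with an estimated correlation; fry adjusted p = 0.00912). Clec1b, Nrgn (2.59), Pf4 (2.41) and Gp1bb (2.22) were among them. Monocyte genes had 9 risen of 14 and none fallen, or 11 and 0 adjusted over the list alone, with a median of 1.70 (adjusted p = 2.75e-07; adjusted p = 0.938 with an estimated correlation). They included Lyz2, Cybb, Csf1r (2.65) and Cd14 (2.42). The higher monocyte and platelet sums stood in the same libraries as the higher NF-kB genes. Of 19 inflammatory genes Tnfsf13 (1.71), a cytokine that sustains B cells, rose and none fell, or 4 and 1 adjusted over the list alone, with a median of 0.70 (adjusted p = 0.021; adjusted p = 0.938 with an estimated correlation). That list had an adjusted p of 0.0914 without normal replicate 2, 0.191 with no filter and 0.116 with a mean of at least 5 TPM.

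Glycolysis and heat shock genes were lower than normal. Of 23 glycolysis genes Pfkl (-1.17) fell and none rose, or 8 and 1 adjusted over the list alone, with a median of -0.36 (adjusted p = 0.00706; adjusted p = 0.938 with an estimated correlation). None of 17 heat shock genes passed, or 5 fell and 0 rose adjusted over the list alone, with a median of -0.28 (adjusted p = 0.021; adjusted p = 0.938 with an estimated correlation). Hsp90ab1 had a log2 fold change of -0.66 (adjusted p = 0.0536). Single genes passed in lists that did not. Tsc22d3 (-1.44), a gene induced by glucocorticoids, Txnip (-0.98), Klf2 (-1.49), Lat (-0.84), a signalling adaptor of the T cell receptor, and the activation markers Cd44 (-1.08) and Cd69 (-1.01) fell. Of interferon-stimulated genes (median -0.14, adjusted p = 0.477), 2 rose and 4 fell, or 2 and 5 adjusted over the list alone, with Mx2 (-1.23), Oasl2 (-1.06) and Oas1b (-1.28) lower and Gbp5 (1.04) higher. Ifngr1 (1.83), a chain of the interferon gamma receptor, Zeb1 (1.43), Ulk1 (1.77) and Rictor (0.96) rose, while Stmn1 (-1.17), Jund (-0.98) and Prdx1 (-0.91) fell.

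Median, mean and test differed in sign for several lists that did not pass between combination and normal. They were the naive T cell (median 0.060, mean -0.068, adjusted p = 0.796), T cell activation (0.014 and 0.055, adjusted p = 0.719), plasma cell (0.020 and -0.063, adjusted p = 0.575), immediate early (0.16 and -0.081, adjusted p = 0.834), unfolded protein response (-0.076 and 0.081, adjusted p = 0.719), erythroid (-0.054 and 0.055, adjusted p = 0.64) and mitochondrially encoded genes (-0.068 and 0.18, adjusted p = 0.719), with a test downward in each. T cell activation and plasma cell medians were negative with median-ratio scaling. TGF-beta genes had a median of 0.27 (adjusted p = 0.102), ribosomal protein genes -0.066 (adjusted p = 0.106) and cell cycle genes -0.074 (adjusted p = 0.64), positive without haemoglobin, mitochondrial and ribosomal protein genes.

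**Figure D4:**
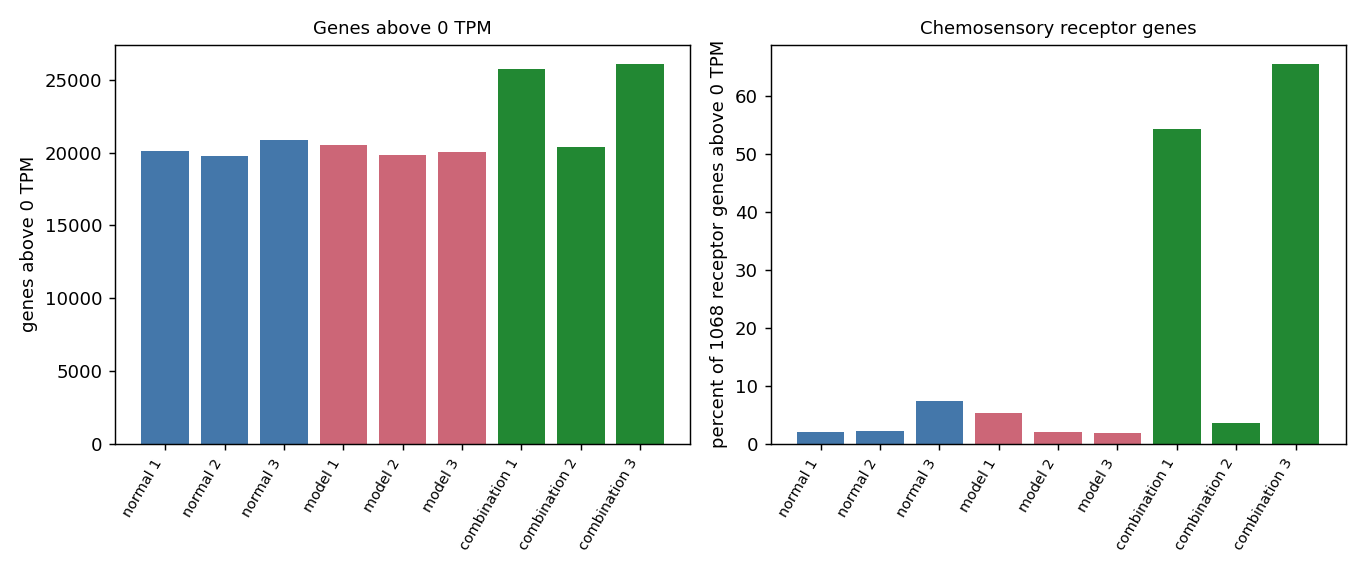
Number of genes above 0 TPM (left, y axis from 0) and percent of chemosensory receptor genes above 0 TPM (right, y axis from 0) in each of the 9 libraries on the x axis. Combination replicates 1 and 3 listed 25724 and 26108 genes, and the other 7 libraries 19769 to 20844. Their receptor shares were 54.3% and 65.5%, against 1.87% to 7.30% in the others.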

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

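The tests of depth, of the compound combination, of a lower share of T cells, of short genes as a class and of the other splits were chosen after the result was seen. The others were set before their results were seen. Combination replicates 1 and 3 listed 25724 and 26108 genes above 0 TPM, against 19769 to 20844 in the other 7 libraries. Depth argued against deeper sequencing as the cause, since the deeper of these 2 libraries had 7.77 gigabases and each of the other 7 at least 8.04. Other causes in sequencing were not tested. The compound combination cannot be told apart: replicate 2 had 20387 genes, but it is 1 library and its low count is part of the pattern itself. Receptor genes of smell and taste were above 0 in a share at least 7.44 times the highest share elsewhere, which is consistent with a background of genomic DNA. RNA from another tissue cannot be told apart for these libraries: a skeletal muscle set of 3 genes reached 4.09 TPM in combination replicate 1 but also 3.65 and 3.93 TPM in normal replicates 1 and 2, and 0.0215 TPM in combination replicate 3, and only 6 tissues were covered by sets of 3 to 5 genes.

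Monocyte and platelet genes were higher in the combination group than in both other groups. A second list of 18 monocyte genes, of which 15 were measured, had medians of 1.15 against model, where 0 members passed, and 1.24 against normal, where 2 passed, so monocytes carried over in the CD4+ preparation may be a source, as rat monocytes also express CD4. Tyrobp averaged 112 TPM against 24.8 and 27.7, while Ctss averaged 49.5 against 47.7 and 43.0 TPM. A second platelet list had a lower median of -0.54 with 4 of 11 genes measured, below the level set in advance as counting against carried-over platelets, but its members spread by 1.29 (SD), a margin applied after the value was seen, so it cannot be told apart; Cd9 was left out after its values were seen, and with it the median was 0.089 and 0.15. A lower share of T cells raises the markers of other cells alike. Against normal the summed monocyte and platelet markers were 4.6 and 4.53 times as high. Those of the other listed blood cells were 0.699 (neutrophil) to 1.28 times (class II and dendritic). Against the model they were 3.23 and 3.51 times, beside 0.0723 (erythroid) to 1.56 times (cytotoxic and NK). These sums argue against a lower share of T cells alone as the source of the higher monocyte and platelet markers. The plasma cell list was also picked for a test of this share after the medians of all lists were seen. The monocyte and platelet medians lay at least 1.68 above its median against either group, more than the joint SD of 0.863 to 1.13. But its fallen members against the model, Xbp1 and Creld2, are also unfolded protein response genes, a list that was lower there (median -0.58). Its median may thus not measure a share of cells. Cytotoxic and NK cell genes had a median of 0.45 against the model group and of 0.085 against the normal group. Both lay below the monocyte and platelet medians.

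Genes of snoRNAs were lower in the model group and higher again in the combination group, with medians of -0.79 and 0.67 over 215 genes. Of these, 150 had 1 measured host gene, and the medians of the 150 were -0.71 and 0.63. The 87 host genes had medians of 0.018 and -0.077, at least 0.745 from the medians of all 215. This argued against host gene expression, measured as TPM, for the 150 as a set. With median-ratio scaling the medians of all 215 stayed at least 0.607 from 0, which argued against scaling. Loss of short genes as a class cannot be told apart: 558 other genes under 300 bases had medians of -0.15 and 0.32, at least 0.348 away, and no value says how far size selection differed between libraries.

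Other splits of the 6 libraries of a comparison gave at most 3 genes against the real 707, 4 against 636 and 4 against 652. In each comparison 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.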

How the results depend on the processing

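Fits with model replicate 2 or combination replicate 2 alone kept, locus sums and fits without short genes or other-cell genes were chosen after the result was seen. Counts are given for model minus normal, combination minus model and combination minus normal, which were 707, 636 and 652. They were 86, 196 and 206 with no filter (30032 genes), of which 71, 125 and 117 were among those above, and 400 and 389 in the last 2 with a mean of at least 5 TPM. They were 1191, 1333 and 1266 with FPKM, 1493, 1630 and 1501 with median-ratio scaling, and 1223, 1426 and 1319 without haemoglobin, mitochondrial and ribosomal protein genes. With only the 2 groups compared they were 113, 24 and 1391, with array weights 2997, 1802 and 3953, and with a replicate block 163, 9 and 82. The main fit shared 1 spread per gene over the 3 groups. Model libraries had a mean correlation of 0.943 to 0.955 with their own group, and normal and combination libraries 0.959 to 0.963. The spread used for 707 and 636 may thus be too small for comparisons with the model group. The cause of the moves in the counts was not tested. Omission of 1 library gave 34 (without normal replicate 2) to 2813 (without model replicate 2), 31 (without combination replicate 2) to 1305 (without model replicate 2) and 21 (without combination replicate 1) to 728 (without combination replicate 3). With model replicate 2 alone kept the first 2 were 55 and 98, and with combination replicate 2 alone kept the last 2 were 14 and 10. In these fits a group held 1 library and the other groups supplied the spread, so the counts do not say what the omitted libraries did. Locus sums gave 728, 682 and 662, and fits without genes under 300 bases 584, 552 and 677. Lists past the threshold numbered 11, 11 and 6. They were 17 and 21 in the first 2 with no filter, 7 and 7 with model replicate 2 alone kept, 6 in combination minus model without other-cell genes, and 0, 0 and 0 with an estimated correlation in camera, where 0, 1 and 1 had an unadjusted p under 0.05 and fry gave 0, 1 and 1 past the threshold. With model replicate 2 alone kept the immediate early list had medians of 0.298 and -0.168 in the first 2 comparisons, while the direction of its camera test turned in both and neither passed (adjusted p = 0.94 and 0.922). In that fit the TGF-beta list had a median of -0.0993 in combination minus model (adjusted p = 0.915). The reversal covariance of -0.177 was -0.325 and -0.0905 with pseudocounts of 0.1 and 5, and -0.187 with a mean of at least 5 TPM.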

Other observations

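The genes and classes in this part were chosen after the values were seen. Some genes changed in the model group and stood changed by a like amount in the combination group. Of 20 measured cytosolic tRNA synthetase genes, a class tallied without a test, 5 rose and none fell against normal in each group, and of 17 mitochondrial ones 0 and 1 rose. Cars (2.46 and 2.63), Iars (1.45 and 1.81), Aars (1.40 and 1.44) and Yars (0.79 and 0.67) rose in both groups. Tsc22d3, a gene induced by glucocorticoids, went from 787 to 295 and 291 TPM and Myc, a regulator of growth, from 129 to 50.6 and 43.4 TPM. In all, 52 genes rose and 60 fell against normal in both groups. Both comparisons use the normal libraries: the covariance of their log2 fold changes was 0.17, against 0.066 in data simulated without group effects, with genes drawn independently. There too each simulated gene had the same spread in all groups. The counts fell to 4 and 3 without normal replicate 2, 4 and 1 without combination replicate 1, and 8 and 9 with the replicate number as a block, and rose to 238 and 533 without model replicate 2. They were 6 and 5, and 5 and 4 without normal replicates 1 and 3, 14 and 26, and 24 and 19 without model replicates 1 and 3, and 6 and 7, and 72 and 57 without combination replicates 2 and 3.

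Genes of snoRNAs, which guide the modification of ribosomal RNA, made up 0.29% to 0.39% of TPM in the normal libraries, 0.17% to 0.22% in the model libraries and 0.27% to 0.36% in the combination libraries. Of 215 such genes 76 fell and none rose in the model group, and 41 rose and none fell in the combination group against the model. The 87 host genes found for 150 of the 215 did not move with them. Levels of the 150 may thus have changed apart from the TPM of their hosts, with medians of -0.71 and 0.63 against 0.018 and -0.077. Only medians of the sets were compared, not each snoRNA with its host, and host transcription was not measured. A loss of short RNA in library making stays open (0.348).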
